A study of Mus musculus with 20 samples.

How the data were processed

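Sorted thymic group 2 innate lymphoid cells (ILC2) of mice were profiled by MARS-seq, a bulk protocol that tags and sequences the 3′ ends of polyadenylated transcripts. Per the labels, thymi were dissociated with Liberase TM and DNase, and ILC2 were sorted into lysis buffer; the labels do not state the sorting gate. The first experiment held 12 libraries of wild-type female mice in 4 groups of 3, and the second held 8 libraries of irradiated male mice in 2 groups of 4. The labels do not state that replicates were separate animals, so every p-value measures only the spread between these samples.

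The authors deposited 1 table per experiment, with raw counts per gene for each library. The deposited normalized values, a signal on the count scale, equal the raw counts divided by 1 size factor per library, and they were not used here. The deposited log2 fold changes are those of the first named group over the second. The deposited p-values and adjusted p-values come from DESeq2 per the labels, and serve here as a comparison only. The labels name bcl2fastq, cutadapt, STAR 2.5.2b, HTSeq and DESeq2 and the build mm10, without settings or an annotation release. The knockout table is named as counts of molecular identifiers; for the treatment table the labels do not say whether identifiers or reads were counted. The tables hold 9973 genes (treatment) and 10706 genes (knockout), each with at least 6 counts in at least 1 library. In the treatment experiment 16 gene names had been turned into dates and 2 entries shared a name; they were kept as separate entries and are not named here. Neither table holds a mitochondrially encoded or an erythroid marker gene.

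Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with edgeR's filterByExpr by group (minimum count 10), which left 7482 genes in the treatment experiment and 8812 in the knockout experiment. Libraries were scaled by the trimmed mean of M-values (TMM), and group differences were tested with edgeR's quasi-likelihood F-test. All 12 treatment libraries shared 1 fit, and the 8 knockout libraries, another cohort of the other sex, had their own. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, and a gene was called at an adjusted p under 0.05. Levels are CPM from edgeR after TMM scaling, given as mean ± SD over the libraries of a group. The SE beside a log2 fold change is the fold change divided by the square root of the F statistic. A fold against a group at 0 counts was computed against a floor of 3 counts over that group and is a lower bound. Where a group held 1 to 3 counts, the ratio of counts per total is given with its exact 95% interval. Intervals and floors cover counting error only.

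The comparisons were irradiated, rIL-25 and both treatments against untreated, both treatments against each single treatment, the interaction, and Il25 knockout against Il25 wild type. The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. That rule took the 6 genes with the largest rise and the 6 with the largest fall among called genes with a mean of at least 10 counts per library in 1 of the groups, leaving out predicted genes. For the comparisons of both treatments with a single one and for the interaction it took 4 each way. It added up to 4 members of each list with the smallest p, and 11 genes in every comparison: Il25, Il17rb, Il1rl1, Gata3, Il5, Il13, Il4, Areg, Klrg1, Cdkn1a and Mki67. Genes named outside the rule are marked in the text.

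The 24 gene lists covered ILC2 identity, type 2 effectors, inflammatory ILC2, tissue residency and egress, cytokine receptors and signalling, p53 and DNA damage response, cell cycle, interferon response, NF-kB and TNF receptor family, apoptosis and survival regulators, thymus regeneration ligands, glycolysis, oxidative phosphorylation, ribosomal proteins, mitochondrially encoded genes, immediate early and dissociation stress genes, and markers of T cells and thymocytes, B cells, myeloid and dendritic cells, NK cells and ILC1, ILC3, mast cells with basophils and eosinophils, stromal with epithelial and endothelial cells, and erythroid cells. Lists of at least 3 tested genes were tested against the other genes with camera (limma 3.58.1), with its preset correlation of 0.01 and with an estimated correlation, and adjusted over the lists of a comparison. For each list, calls are given over all genes and adjusted over the list alone. Another 2 lists, of tuft cell and of early progenitor genes, were added after the data were seen.

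Alternatives were DESeq2's size factors (RLE) in edgeR, no filter, a filter with minimum count 30, the replicate number as a block, a threshold of at least 2-fold, only the 2 groups compared, DESeq2 1.42.0, limma voom with sample quality weights, and each library left out in turn. Added after seeing the data were an offset per library for the GC content of the last 500 transcript bases, sets of libraries left out together, and lists from the comparisons with both treatments. Genes were matched by symbol to GENCODE M21 for position and GC content, which gave values for 99.4% and 99.5% of the genes of the tables. The test was tried on simulated data with these libraries' depths and spread: in the untreated and irradiated groups it recovered 40% of 2-fold and 87.6% of 4-fold changes with 3.9% false calls, and in the knockout experiment 80.9% and 99% with 3.9% false calls. Replicate libraries differed by more than counting error, with a chi-square per degree of freedom of 2.34 to 14.53 over 24 pairs. Deviations of libraries with the same number in the sample titles correlated weakly across groups (from −0.197 to 0.246), so no pairing was used. In both treatments against irradiated, however, all 6 libraries correlated best with their own number (0.011 to 0.104, against −0.092 to 0.009 for other numbers).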

Results

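Thymic ILC2, lymphocytes that make type 2 cytokines such as IL-5 and IL-13, were sorted from wild-type female mice in 4 groups of 3 libraries. The mice were untreated, irradiated with a sublethal dose of 425 rad, injected into the thymus with 0.3 µg of recombinant IL-25 (rIL-25), or given both treatments, for 3 days. No group was injected without rIL-25. Every comparison with rIL-25 therefore holds the injection too, and the 2 cannot be told apart. IL-25 is a cytokine that tuft cells release and that ILC2 detect through a receptor containing Il17rb. A second experiment compared irradiated male mice with and without a working Il25 gene, with 4 libraries per group. Total counts of replicates 1 to 3 were 639558, 696441 and 799814 in untreated mice and 666791, 542626 and 495079 after irradiation. They were 747018, 1460702 and 769525 after rIL-25, and 587533, 761463 and 1357518 after both treatments. In the knockout experiment the totals of replicates 1 to 4 were 3860726, 4420831, 3610767 and 3201179 in Il25 wild-type mice and 4149389, 3031807, 2323756 and 2093288 in Il25 knockout mice. Without TMM scaling, 3 counts in 1 library of the treatment experiment corresponded to between 2.05 and 6.06 CPM. In the knockout experiment they corresponded to between 0.68 and 1.43 CPM, also without TMM scaling.

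The first comparison asked how libraries of sorted thymic ILC2 differed 3 days after sublethal irradiation. Cd3d, a chain of the T cell receptor complex (chromosome 9, 44981786 to 44987339 in mm10), rose from 117 ± 10.4 to 676 ± 27.0 CPM (n = 3 per group), a 5.76-fold difference with an adjusted p of 2.4e-08. Id2, a regulator that innate lymphoid cells need, rose from 32.6 ± 21.0 to 193 ± 82.8 CPM, Thy1 from 1483 ± 316 to 3380 ± 822 CPM, and the adhesion molecule Cd2 from 13.3 ± 4.90 to 217 ± 70.6 CPM. Dntt, the polymerase that adds nucleotides during antigen receptor rearrangement, fell from 2153 ± 189 to 966 ± 64.2 CPM, and the mast cell protease Cpa3 fell from 298 ± 52.4 to 49.7 ± 18.2 CPM. The homeobox gene Hoxa7 fell from 129 ± 77.7 to 14.7 ± 3.05 CPM and Scin, which severs actin filaments, from 147 ± 37.0 to 17.6 ± 7.25 CPM. In total edgeR called 301 of 7482 genes, 166 higher and 135 lower. Of these, 216 changed at least 2-fold.

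Among the largest rises after irradiation, Pdlim4 rose by 4.92 ± 0.63 and Drc1 by 4.48 ± 0.50 on the log2 scale. Asb2, with 0 counts in untreated mice, reached 32.9 ± 18.5 CPM, at least 23.2-fold higher, and Il2rb, a chain of the IL-2 and IL-15 receptors, was at least 10.2-fold higher. Both lost their calls without untreated replicate 1, untreated replicate 3 or irradiated replicate 3 (adjusted p up to 0.0784 for Asb2 and 0.0886 for Il2rb). The lists showed the following. Of 16 measured ILC2 identity genes, 2 rose (Id2 and Thy1) and 2 fell (6 and 2 adjusted over the list alone), with no call for the list (adjusted p = 0.0702). The stem cell factor receptor Kit, 1 of the pair that fell, went to 26.6 ± 13.5 CPM, a call lost without untreated replicate 3 (adjusted p = 0.0616). The ILC2 master regulator Gata3, at 211 ± 23.5 and 249 ± 52.6 CPM, and Il17rb, at 202 ± 6.48 and 203 ± 27.8 CPM, were not called. None of 5 measured type 2 effectors was called over all genes, but 3 rose adjusted over the list alone and the list was higher (adjusted p = 0.00152, but adjusted p = 0.172 with an estimated correlation). Il13 was at 2.22 ± 1.95 and 20.1 ± 10.4 CPM (adjusted p = 0.196). The IL-33 receptor gene Il1rl1 had a count ratio of 20.9 (95% interval 6.71 to 105) with an adjusted p of 0.0526, which came under 0.05 without irradiated replicate 1 or 2 or any 1 of the rIL-25 libraries (lowest 0.0091).

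Of 72 oxidative phosphorylation genes, 16 rose and 0 fell (35 and 0 adjusted over the list alone), a call that held with an estimated correlation (adjusted p = 1.82e-17, and adjusted p = 0.0247 with an estimated correlation). Cox6a1 rose from 1108 ± 157 to 2246 ± 204 CPM and Ndufa1 from 156 ± 19.3 to 305 ± 52.6 CPM. None of 10 glycolysis genes was called (2 higher adjusted over the list alone), and their list was higher (adjusted p = 0.00415, but adjusted p = 0.172 with an estimated correlation). Of 74 ribosomal protein genes, 5 rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 3.1e-07, but adjusted p = 0.172 with an estimated correlation). Activation genes included the inflammatory ILC2 list, of which 2 of 8 rose and 1 fell (3 and 1 adjusted over the list alone), and the NF-kB and TNF receptor list, of which 3 of 13 rose (6 adjusted over the list alone). Their adjusted p-values were 0.00415 and 0.000712, and each gave an adjusted p = 0.172 with an estimated correlation. S100a4 rose from 9.73 ± 6.51 to 133 ± 35.0 CPM, S100a6 from 19.8 ± 5.22 to 81.5 ± 10.5 CPM, and the cytokine gene Lta from 2.65 ± 1.06 to 16.7 ± 1.81 CPM. Lta was also the 1 gene of 8 thymus regeneration ligands that rose (1 adjusted over the list alone), and 3 of 11 residency and egress genes rose (5 higher and 1 lower adjusted over the list alone). These lists had adjusted p-values of 0.00448 and 0.0083, each with an adjusted p = 0.172 with an estimated correlation. Of 21 cytokine receptor and signalling genes, 3 rose and 1 fell (6 and 3 adjusted over the list alone; adjusted p = 0.257), among them Cish, a feedback inhibitor of cytokine signalling, from 29.8 ± 7.84 to 97.2 ± 10.9 CPM.

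Radiation response genes moved both ways: of 18 p53 and DNA damage genes, 5 rose and 2 fell (6 and 3 adjusted over the list alone; adjusted p = 0.39). 9030617O03Rik rose from 2.59 ± 1.95 to 32.5 ± 11.2 CPM and the DNA repair gene Ddb2 fell from 63.5 ± 9.96 to 23.2 ± 4.89 CPM, while Cdkn1a, at 44.3 ± 15.2 and 46.8 ± 8.32 CPM, was not called. The irradiated cohorts differed in Cdkn1a: irradiated male Il25 wild-type mice of the second experiment, which had no untreated group, were at 381 ± 33.2 CPM. Of 40 cell cycle genes 0 rose and 1 fell (1 and 1 adjusted over the list alone; adjusted p = 0.39), and Mki67 was at 268 ± 20.5 and 280 ± 36.2 CPM. Of 23 interferon response genes 1 rose (3 adjusted over the list alone; adjusted p = 0.0365, but adjusted p = 0.328 with an estimated correlation). Of 16 immediate early and dissociation stress genes 3 fell (4 adjusted over the list alone; adjusted p = 0.046, but adjusted p = 0.336 with an estimated correlation), and of 15 apoptosis and survival regulators 1 rose (1 adjusted over the list alone; adjusted p = 0.897). Markers of other cell types moved beside these groups. Of 11 T cell and thymocyte markers 3 rose and 1 fell (3 and 1 adjusted over the list alone), and the list was higher (adjusted p = 5.79e-05, and adjusted p = 0.0247 with an estimated correlation). Its members Cd4 and Cd8a, named after their values were seen, had low counts that did not rise. Cd4 had 11 counts in untreated, 3 in irradiated and 5 in doubly treated libraries together, and Cd8a had 13, 4 and 8. The members Trac, Trbc1 and Trbc2 were not measured. Of 3 NK cell and ILC1 markers, the protease Gzma rose from 367 ± 55.6 to 967 ± 164 CPM (1 higher and 1 lower adjusted over the list alone; adjusted p = 0.157 for the list). None of 7 myeloid markers (adjusted p = 0.179) or 4 stromal, epithelial and endothelial markers (adjusted p = 0.39) was called, also adjusted over the list alone. Cd79b, the only tested B cell marker, fell from 65.5 ± 8.13 to 33.5 ± 2.18 CPM, a call lost without any 1 of the 6 libraries compared (adjusted p up to 0.145). Cpa3 and Nrp1 (12.9 ± 8.35 and 24.2 ± 1.40 CPM, not called) were the only tested markers of mast cells and related cells and of ILC3, and no erythroid or mitochondrially encoded gene was measured. The interferon list lost its call without untreated replicate 2 or irradiated replicate 3 (adjusted p up to 0.217), and dissociation stress without untreated replicate 2, irradiated replicate 1 or 3 or doubly treated replicate 2 (up to 0.27). ILC2 identity was called without untreated replicate 3, irradiated replicate 1, doubly treated replicate 1 or any 1 of the rIL-25 libraries (lowest 0.0128), and myeloid markers without irradiated replicate 1 or rIL-25 replicate 3 (0.0228 and 0.032). The count of 301 genes was 148, 86, 146 and 109 without untreated replicate 1, untreated replicate 3, irradiated replicate 1 and irradiated replicate 3, and 541 by limma voom. Of the 55 called genes that the naming rule took, 20 were called in every fit with 1 library left out, and the called genes named here are among them unless a lost call is given.

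The second comparison asked how libraries differed after injection of rIL-25 alone. No gene passed: edgeR called 0 of 7482 genes, with 336 at an unadjusted p under 0.05, DESeq2 and limma voom also called 0, and the authors' deposited table called 3. The type 2 cytokine Il13 was at 2.22 ± 1.95 CPM in untreated mice and 24.8 ± 33.8 CPM after rIL-25 (n = 3 per group), with 63.6 CPM in rIL-25 replicate 3. Replicates 1 to 3 after rIL-25 had 4, 17 and 285 counts of the antigen presentation gene H2-Aa (9 in all untreated mice) and 4, 8 and 86 of Cd74, of the same pathway (3 untreated). They had 0, 7 and 38 counts of Klrg1, a surface marker of activated ILC2 (3 untreated), and 0, 0 and 19 of Il1rl1 (3 untreated), so these values rested on replicate 3. Il17rb was at 202 ± 6.48 and 218 ± 32.8 CPM, Gata3 at 211 ± 23.5 and 187 ± 20.2 CPM, and Mki67 at 268 ± 20.5 and 264 ± 83.9 CPM.

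As a group, all 7 measured myeloid and dendritic cell markers passed and were higher adjusted over the list alone, and 0 over all genes (adjusted p = 6.47e-10, but adjusted p = 0.348 with an estimated correlation). Of 5 type 2 effectors and 8 inflammatory ILC2 genes, 3 each were higher adjusted over the list alone, and of 11 residency genes 0, with adjusted p-values of 0.00975, 0.0137 and 0.0137. Oxidative phosphorylation (72 genes) and ribosomal protein genes (74) were higher as lists, with 0 called adjusted over the list alone (adjusted p = 0.00186 and 0.002). With an estimated correlation the adjusted p was 0.475 for ribosomal proteins and 0.348 for each of the other lists called. Without rIL-25 replicate 3 the myeloid list stayed called with its median log2 change down from 2.157 to 0.69 (adjusted p = 0.00191), while type 2 effectors, inflammatory ILC2 and residency lost their calls (0.683 each). Type 2 effectors also lost theirs without untreated replicate 2, inflammatory ILC2 without untreated replicate 1 or 2 or irradiated replicate 2, and residency without untreated replicate 1 or 2 (adjusted p up to 0.64). Oxidative phosphorylation and ribosomal proteins lost theirs without rIL-25 replicate 2 (0.0593 and 0.124). The lists not called were ILC2 identity (adjusted p = 0.127), cytokine receptors (0.535), p53 (0.863), interferon response (0.0606), NF-kB (0.0593), thymus regeneration ligands (0.171), dissociation stress (0.311) and T cell markers (0.509). Cell cycle, apoptosis, glycolysis, NK cell and stromal markers were not called either (0.636 each). None of these lists had a gene called adjusted over the list alone. Of them ILC2 identity, NF-kB, interferon, thymus regeneration ligands and stromal markers were called in 2, 6, 10, 3 and 8 of the 12 fits with 1 library left out (lowest adjusted p 0.0159, 0.00492, 0.00217, 0.0264 and 0.00146). Leaving out untreated replicate 2 gave 3 calls (Cox7b, Atp5k and Rpl39, adjusted p from 0.00625), and leaving out rIL-25 replicate 2 gave 3 others (H2-Aa, H2-Ab1 and H2-Eb1, adjusted p = 0.0374); Atp5k was named after its value was seen. The authors' calls were H2-Aa, Wsb2 and 1810022K09Rik, the last pair named after their values were seen.

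The third comparison asked how libraries of sorted ILC2 differed after both treatments. Il13 (chromosome 11, 53631324 to 53634702) rose from 2.22 ± 1.95 to 161 ± 129 CPM (5 and 547 counts, n = 3 per group), with an adjusted p of 0.000276. Arg1, an enzyme of arginine breakdown made by ILC2, had a count ratio of 110 (95% interval 30.1 to 912), Il1rl1 35.7 (11.9 to 175) and Klrg1 41.9 (14.1 to 205), and all were called higher. Doubly treated replicates 1 to 3 had 43, 26 and 202 counts of Arg1, so much of its ratio came from replicate 3. Il1rl1 was not called by DESeq2 (adjusted p = 0.11). Asb2 was at least 64.6-fold higher, Il2rb at least 27.8-fold, Ramp3 at least 16.5-fold and the protease gene Adam19 at least 13.8-fold, each from 0 counts in untreated mice. Cpa3 fell from 298 ± 52.4 to 25.5 ± 31.2 CPM and Dntt from 2153 ± 189 to 1152 ± 271 CPM. In total 668 genes were called, 316 higher and 352 lower. Of these, 482 changed at least 2-fold. Untreated libraries together held 3 counts each of Il1rl1 and Klrg1 and 2 of Arg1, beside Dntt at 2153 ± 189 CPM. Whether rises of ILC2 genes, here and after irradiation alone, came from a changed mix of sorted cells or from a change within ILC2 was not tested.

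After both treatments 4 of 5 type 2 effectors rose (5 adjusted over the list alone; adjusted p = 2.38e-07, and adjusted p = 0.0273 with an estimated correlation). Among them the lipid enzyme gene Dgat2 had a count ratio of 95.7 (16.8 to 3810) and Furin rose from 12.4 ± 1.41 to 72.6 ± 18.5 CPM. Of 16 ILC2 identity genes 7 rose and 1 fell (7 and 2 adjusted over the list alone; adjusted p = 0.000901, and adjusted p = 0.0273 with an estimated correlation). Id2 rose from 32.6 ± 21.0 to 446 ± 95.9 CPM and Tcf7, a regulator of early innate lymphoid and T cell development, from 131 ± 11.7 to 471 ± 332 CPM, while Kit fell by 1.61 ± 0.30 on the log2 scale. Of 8 inflammatory ILC2 genes 5 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.000499, and adjusted p = 0.0357 with an estimated correlation). S100a4 rose by 4.44 ± 0.55 and S100a6 by 2.34 ± 0.38 on the log2 scale. Of 13 NF-kB and TNF receptor genes 7 rose (8 adjusted over the list alone; adjusted p = 3.38e-09, and adjusted p = 0.0273 with an estimated correlation). Lta rose from 2.65 ± 1.06 to 37.9 ± 5.47 CPM, Ltb from 158 ± 48.7 to 556 ± 23.5 CPM, and Tnfrsf18, which encodes the receptor GITR, from 37.1 ± 3.33 to 165 ± 26.1 CPM. Lta, Ltb and Il13 were among the 4 of 8 thymus regeneration ligands that rose (6 adjusted over the list alone; adjusted p = 2.94e-07, and adjusted p = 0.0273 with an estimated correlation).

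Of 21 cytokine receptor and signalling genes 7 rose (7 and 2 lower adjusted over the list alone; adjusted p = 0.0143, but adjusted p = 0.209 with an estimated correlation), and their median log2 change of −0.01 had the opposite sign to the test. Cish rose 7.23-fold and Socs1, another feedback inhibitor, 2.81-fold. Of 11 residency and egress genes 5 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.0051, but adjusted p = 0.178 with an estimated correlation). The integrin gene Itgae rose from 2.02 ± 3.49 to 46.2 ± 10.2 CPM. Of 10 glycolysis genes 2 rose (3 adjusted over the list alone; adjusted p = 0.0109, but adjusted p = 0.217 with an estimated correlation). Lists without a call were p53 (4 of 18 rose and 2 fell; 6 and 4 adjusted over the list alone; adjusted p = 0.46) and cell cycle (2 of 40 rose, also adjusted over the list alone; adjusted p = 0.201). The mitotic gene Cdc20 rose from 185 ± 21.4 to 335 ± 40.5 CPM and Mki67 was at 268 ± 20.5 and 247 ± 59.2 CPM. Interferon genes (1 of 23 rose; 5 and 1 lower adjusted over the list alone; adjusted p = 0.11) included Ifi27l2a, 4.68-fold higher. Oxidative phosphorylation (2 of 72 rose and 1 fell; 0 adjusted over the list alone; adjusted p = 0.0807) and apoptosis regulators (3 of 15 rose, also adjusted over the list alone; 0.46) were not called. Neither were ribosomal proteins (4 of 74 fell, also adjusted over the list alone; 0.46) and dissociation stress (1 of 16 rose and 2 fell; 2 and 3 adjusted over the list alone; 0.847).

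Markers of other cell types moved beside these groups after both treatments. Of 11 T cell and thymocyte markers 4 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.00015, and adjusted p = 0.0273 with an estimated correlation). Cd3d rose from 117 ± 10.4 to 491 ± 70.6 CPM and Rag1, a recombinase of early lymphocytes, from 24.5 ± 16.1 to 74.8 ± 6.84 CPM, while Dntt fell. Of 7 myeloid markers 1 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.17), of 3 NK cell markers 1 rose and 1 fell (2 and 1 adjusted over the list alone; 0.46), and of 4 stromal markers 0 were called (0.769). The share of counts from ribosomal protein genes was 20.8% and 21.0% in replicates 1 and 3 of the doubly treated group and 26.2% in replicate 2. Of the lists not called, interferon, myeloid and stromal markers were called without doubly treated replicate 3 (adjusted p = 0.0281, 0.0281 and 0.0413), and myeloid markers also without rIL-25 replicate 3. Oxidative phosphorylation was called without doubly treated replicate 1 or untreated replicate 2 (0.00238 and 0.017), and ribosomal proteins without doubly treated replicate 2 (0.0109). The count of 668 was 357 without untreated replicate 2, 424 without untreated replicate 3 and 271 without doubly treated replicate 3, and with doubly treated replicates 1 and 3 both left out, a choice made after the data were seen, it was 37. Of 68 called genes that the naming rule took, 42 were called in every fit with 1 library left out, and the called genes named here are among them.

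**Figure D1:**
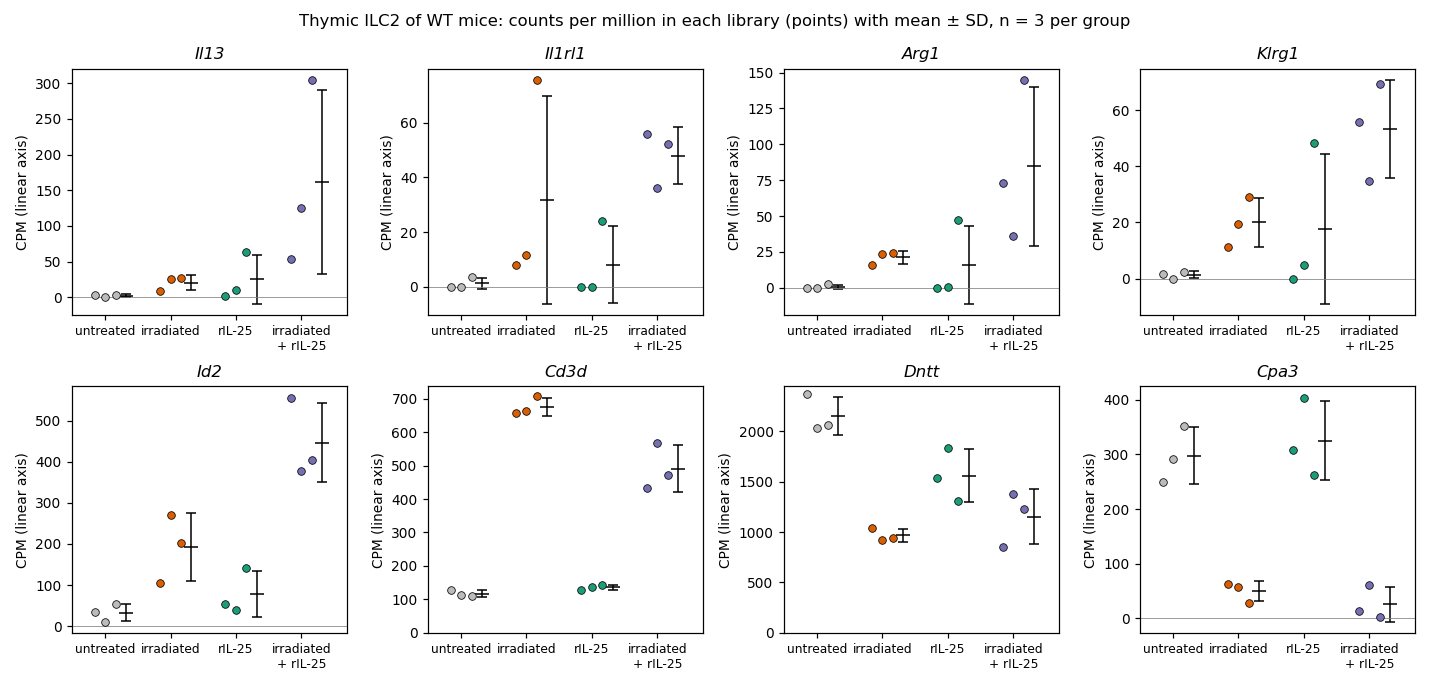
Levels of 8 genes in the 12 libraries of the treatment experiment, in CPM, with each library as a point and the mean ± SD of each group of 3 as a bar. Il13 had its highest group mean, 161 CPM, after both treatments, and Cd3d was higher in both irradiated groups (676 and 491 CPM) than in untreated mice (117 CPM) and mice given rIL-25 (135 CPM).

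The fourth comparison asked what injection of rIL-25 added in irradiated mice, without a group injected otherwise. Il13 was higher after both treatments than after irradiation alone, at 161 ± 129 against 20.1 ± 10.4 CPM (n = 3 per group, adjusted p = 0.0172), a call lost without irradiated replicate 1, irradiated replicate 3 or doubly treated replicate 3 (adjusted p up to 0.194). Among genes lower after both treatments, the ribosomal protein gene Rpl39 fell from 1191 ± 63.3 to 160 ± 73.4 CPM, Cox7b from 973 ± 206 to 237 ± 38.8 CPM, Uqcrb from 183 ± 71.9 to 37.6 ± 17.0 CPM and Ndufa5 from 207 ± 35.4 to 56.5 ± 17.1 CPM. Cept1, an enzyme of phospholipid synthesis, fell from 29.9 ± 7.41 to 4.65 ± 1.13 CPM, and Ccng1, a p53 target, from 88.6 ± 24.5 to 30.4 ± 9.09 CPM. In total 188 genes were called, 48 higher and 140 lower. Of these, 156 changed at least 2-fold.

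Of 72 oxidative phosphorylation genes 11 fell and 0 rose (19 fell adjusted over the list alone), and of 74 ribosomal protein genes 7 fell and 0 rose (18 fell adjusted over the list alone). Their adjusted p-values were 6.84e-11 and 8.32e-11, but adjusted p = 0.159 and adjusted p = 0.184 with an estimated correlation. Of 5 type 2 effectors 2 rose (3 adjusted over the list alone), of 16 ILC2 identity genes 1 rose (4 adjusted over the list alone), and of 8 thymus regeneration ligands 1 rose (3 adjusted over the list alone). These lists were higher with adjusted p-values of 0.00174, 0.025 and 0.00206, each with an adjusted p = 0.184 with an estimated correlation. The 1 ILC2 identity gene was Bcl11b, a regulator of ILC2 and T cells, which rose from 81.2 ± 11.1 to 154 ± 9.65 CPM and lost its call without irradiated replicate 1 or 3 (adjusted p up to 0.0798). None of 13 NF-kB genes was called over all genes (4 rose adjusted over the list alone; adjusted p = 0.00174, but adjusted p = 0.216 with an estimated correlation). Of 16 dissociation stress genes 1 rose and 1 fell (2 and 1 adjusted over the list alone; adjusted p = 0.025, but adjusted p = 0.437 with an estimated correlation). Il1rl1 (31.9 ± 38.1 and 48.0 ± 10.5 CPM), Klrg1 (30 and 155 counts), Il17rb (203 ± 27.8 and 199 ± 42.2 CPM) and Cd3d (676 ± 27.0 and 491 ± 70.6 CPM) were not called.

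The other lists were not called: inflammatory ILC2 (0 of 8; adjusted p = 0.32), residency (0 of 11; 0.711), cytokine receptors (1 of 21 rose, also adjusted over the list alone; 0.104), p53 (1 of 18 fell, 3 adjusted over the list alone; 0.967) and cell cycle (1 of 40 fell, also adjusted over the list alone; 0.711). Neither were interferon (0 of 23; 0.889), apoptosis (0 of 15; 0.586) and glycolysis (0 of 10; 0.967). Markers of T cells (0 of 11, 1 rose adjusted over the list alone; adjusted p = 0.967), myeloid cells (0 of 7; 0.864), NK cells (0 of 3; 0.711) and stromal cells (0 of 4, 1 rose adjusted over the list alone; 0.406) were not called either. ILC2 identity lost its list call without irradiated replicate 1 or 2 (adjusted p up to 0.0708), and dissociation stress without irradiated replicate 1 or 3 or doubly treated replicate 1 (up to 0.229). Cytokine receptors were called without irradiated replicate 1, rIL-25 replicate 1 or 2 or any 1 of the untreated libraries (lowest 0.0314). The count of 188 was 83 without irradiated replicate 1, 93 without irradiated replicate 3, and 125, 358 and 42 without doubly treated replicates 1, 2 and 3. It was 0 with doubly treated replicates 1 and 3 both left out (unadjusted p under 0.05 for 552 genes in edgeR), and 125 in a fit of these 2 groups alone. Of 21 called genes that the naming rule took, 8 were called in every fit with 1 library left out.

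The fifth comparison asked what irradiation added in mice given rIL-25. Cd3d rose from 135 ± 8.47 to 491 ± 70.6 CPM (n = 3 per group, adjusted p = 3.87e-06), Id2 from 77.6 ± 55.5 to 446 ± 95.9 CPM and Pdlim4 from 1.97 ± 1.76 to 120 ± 59.3 CPM. Il13 rose from 24.8 ± 33.8 to 161 ± 129 CPM (adjusted p = 0.00418), a call lost without doubly treated replicate 3 (adjusted p = 0.075). Angpt1, a growth factor for vessels and stem cells, fell from 48.9 ± 19.3 to 3.78 ± 2.66 CPM and Cpa3 from 325 ± 72.1 to 25.5 ± 31.2 CPM. Rpl39 fell by 2.75 ± 0.31 on the log2 scale. In total 1142 genes were called, 487 higher and 655 lower. Of these, 742 changed at least 2-fold.

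All 5 type 2 effectors rose, also adjusted over the list alone (adjusted p = 0.000298, but adjusted p = 0.153 with an estimated correlation). Of 13 NF-kB genes 6 rose (8 adjusted over the list alone; adjusted p = 1.44e-05) and of 8 thymus regeneration ligands 5 rose (5 adjusted over the list alone; adjusted p = 9.41e-05), but both had an adjusted p = 0.138 with an estimated correlation. Lta rose 7.65-fold, Ltb 3.31-fold and the cytokine gene Lif 4.33-fold. Of 16 ILC2 identity genes 5 rose and 2 fell (7 and 2 adjusted over the list alone, adjusted p = 0.0317, but adjusted p = 0.164 with an estimated correlation), with Tcf7 3.15-fold higher and Kit at −1.70 ± 0.30 on the log2 scale. Tcf7 varied widely between the doubly treated libraries, from 259 to 853 CPM. Of 8 inflammatory ILC2 genes 4 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.0482), and of 10 glycolysis genes 2 rose (4 adjusted over the list alone; adjusted p = 0.0201). Both had an adjusted p = 0.297 with an estimated correlation. S100a4 rose 6.28-fold, Klf2 3.60-fold and the lactate dehydrogenase gene Ldha 2.13-fold. Of 74 ribosomal protein genes 1 rose and 12 fell (2 and 14 adjusted over the list alone; adjusted p = 0.0361, but adjusted p = 0.619 with an estimated correlation). Of 72 oxidative phosphorylation genes 3 rose and 7 fell (2 and 6 adjusted over the list alone; adjusted p = 0.984). Rps24 fell from 4453 ± 410 to 1420 ± 868 CPM, while Uqcrfs1 rose from 245 ± 26.1 to 432 ± 40.4 CPM.

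Of 11 T cell and thymocyte markers 4 rose (5 adjusted over the list alone), the list call that held with an estimated correlation (adjusted p = 0.000113, and adjusted p = 0.0379 with an estimated correlation). Of 7 myeloid markers 3 fell (4 adjusted over the list alone; adjusted p = 0.077). Tyrobp fell from 52.8 ± 29.2 to 4.95 ± 2.03 CPM, and H2-Ab1 and Lyz2 lost their calls without rIL-25 replicate 3 (adjusted p = 0.519 and 0.604). Of 3 NK cell markers Gzma rose and Nkg7 fell, also adjusted over the list alone (adjusted p = 0.76), and 0 of 4 stromal markers were called (0.984). Lists without a call were cytokine receptors (6 of 21 rose and 1 fell, also adjusted over the list alone; adjusted p = 0.0646), residency (2 of 11 rose and 1 fell; 3 and 1 adjusted over the list alone; 0.206) and p53 (3 of 18 rose and 1 fell; 4 and 3 adjusted over the list alone; 0.669). Also without a call were cell cycle (4 of 40 rose and 3 fell, also adjusted over the list alone; 0.503) and interferon (1 of 23 rose and 1 fell, also adjusted over the list alone; 0.728). The same held for apoptosis (3 of 15 rose and 1 fell, also adjusted over the list alone; 0.749) and dissociation stress (1 of 16 rose and 3 fell, also adjusted over the list alone; 0.76). Among their members Cish rose 4.09-fold and Bax 1.95-fold, Cdc20 rose from 169 ± 24.9 to 335 ± 40.5 CPM and Ccna2 fell from 259 ± 44.5 to 111 ± 54.8 CPM. Lists that lost their call were ILC2 identity without rIL-25 replicate 2 (adjusted p = 0.0678), glycolysis without doubly treated replicate 1 (0.0546), and ribosomal proteins without rIL-25 replicate 1 or 2 or doubly treated replicate 1 or 3 (up to 0.199). Inflammatory ILC2 lost its call without rIL-25 replicate 1 or 2, doubly treated replicate 1 or 2 or irradiated replicate 3 (up to 0.123). Myeloid markers were called without rIL-25 replicate 1 or 2 (lowest 0.00217), residency without rIL-25 replicate 3 (0.00433), and cytokine receptors in 8 of the 12 fits with 1 library left out (lowest 0.00433). The count of 1142 was 612 without rIL-25 replicate 1, 460 without doubly treated replicate 3 and 34 with doubly treated replicates 1 and 3 both left out. Of 73 called genes that the naming rule took, 48 were called in every fit with 1 library left out.

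The sixth comparison asked whether irradiation acted differently with an injection of rIL-25 than without it. Rpl39 differed most strongly: its log2 change after irradiation was 1.10 without and −2.75 with rIL-25, a difference of −3.85 ± 0.42 (n = 3 per group, adjusted p = 5.64e-05). Its level also varied within 1 condition, from 21.7 to 442 CPM among Il25 knockout libraries. Irradiated Il25 wild-type mice of the second experiment averaged 50.5 CPM, against 1190 CPM in irradiated mice of the first. Uqcrb (−3.07 ± 0.49), Cept1 (−3.76 ± 0.62) and Cox7b (−2.88 ± 0.45) differed the same way, as did Ndufa5 (−2.63 ± 0.38) and Ndufa1 (−1.60 ± 0.26). Bccip, a cell cycle and DNA repair gene, went the other way (2.40 ± 0.40), from −0.70 without to 1.70 with rIL-25. In total 155 genes were called, 27 with a higher and 128 with a lower change when rIL-25 was given, and all 155 differences were at least 2-fold. Of 72 oxidative phosphorylation genes 9 were called lower and 0 higher (23 and 2 adjusted over the list alone), and of 74 ribosomal protein genes 8 and 0 (19 and 0 adjusted over the list alone). Their adjusted p-values were 2.3e-10 and 3.11e-10, but adjusted p = 0.19 and adjusted p = 0.341 with an estimated correlation.

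None of the 7 myeloid markers differed over all genes (5 lower adjusted over the list alone), and their list was lower (adjusted p = 0.00993, but adjusted p = 0.827 with an estimated correlation), a call lost without rIL-25 replicate 3 (adjusted p = 0.315). The effect of irradiation on Il13 did not differ detectably (−0.18 ± 1.15 on the log2 scale, adjusted p = 0.961), nor did it on Il1rl1 (adjusted p = 0.704), Klrg1 (0.525), Il17rb (0.854) or Cd3d (0.168). The remaining lists were not called: interferon, dissociation stress (1 lower; 1 higher and 1 lower adjusted over the list alone) and thymus regeneration ligands at an adjusted p of 0.623 each. Residency was at 0.682 (2 higher and 4 lower adjusted over the list alone), NF-kB at 0.711, and p53 at 0.98 (1 lower, 3 adjusted over the list alone). Cell cycle (1 lower, 2 adjusted over the list alone) and glycolysis were at 0.819, and ILC2 identity (1 higher), type 2 effectors, inflammatory ILC2, apoptosis, cytokine receptors, T cell, NK cell and stromal markers at 0.754. The count of 155 was 29, 347 and 44 without untreated replicates 1, 2 and 3, 80 and 74 without irradiated replicates 1 and 3, and 77 without rIL-25 replicate 1. It was 289 and 50 without doubly treated replicates 2 and 3, 1 (Rpl39, named by the rule) with doubly treated replicates 1 and 3 both left out, and 417 by limma voom. Of 18 called genes that the naming rule took, 9 were called in every fit with 1 library left out, and the called genes named here are among them.

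**Figure D2:**
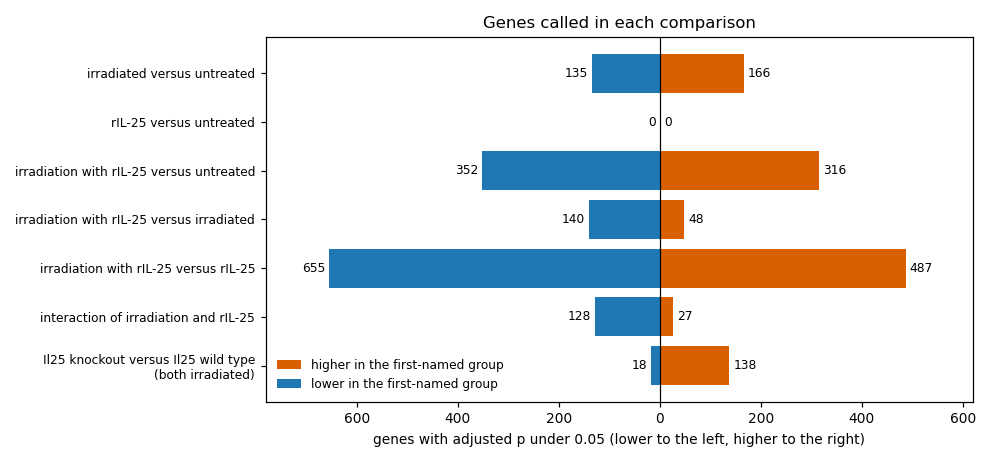
Number of genes called higher and lower in each of the 7 comparisons, as bars from 0. The first-named group of each comparison is the one in which genes were higher or lower, and for the interaction the bars count differences between effects; the counts run from 0 for rIL-25 against untreated to 1142 for both treatments against rIL-25.

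The seventh comparison asked how libraries of sorted ILC2 of irradiated mice differed without Il25. Il25 itself had 3, 7, 17 and 10 counts in the Il25 wild-type libraries and 0 in all 4 knockout libraries. Without TMM scaling, its wild-type level was 2.55 ± 1.74 CPM (n = 4), at least 9.48-fold higher than in knockout mice. This bound is therefore not on the TMM scale of the other levels. The labels do not say which part of the gene was deleted. Type 2 cytokine genes were higher in the knockout: Il13 rose from 22.6 ± 2.60 to 78.1 ± 16.5 CPM (3.43-fold, adjusted p = 3.45e-05) and the growth factor gene Areg from 23.4 ± 6.40 to 67.9 ± 2.15 CPM (2.93-fold). The galectin gene Lgals3 (chromosome 14, 47367751 to 47386160) rose by 2.65 ± 0.22 on the log2 scale, the costimulatory receptor gene Icos from 3.16 ± 1.49 to 19.5 ± 1.36 CPM, and the granzyme gene Gzmb from 39.6 ± 12.7 to 110 ± 29.3 CPM. Dntt fell from 953 ± 143 to 597 ± 56.5 CPM and Ccng2 from 15.5 ± 3.30 to 4.92 ± 2.07 CPM. In total 156 of 8812 genes were called, 138 higher and 18 lower. Of these, 92 changed at least 2-fold.

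Of 11 type 2 effectors 8 rose (9 adjusted over the list alone; adjusted p = 1.92e-30, and adjusted p = 0.0022 with an estimated correlation). Besides Il13 and Areg they included the chemokine gene Ccl1 (7.45-fold), the neuropeptide gene Calca (2.82-fold) and Furin (2.20-fold). Il5 rose from 2.19 ± 1.33 to 8.13 ± 2.80 CPM, a call lost without wild-type replicate 1, 2 or 3 or knockout replicate 2, 3 or 4 (adjusted p up to 0.0851). Il4 was at 1.86 ± 1.27 and 6.36 ± 2.74 CPM (adjusted p = 0.0628) and passed without wild-type replicate 4 or knockout replicate 2 (lowest 0.0133). Of 17 ILC2 identity genes 5 rose (6 and 2 lower adjusted over the list alone; adjusted p = 7.95e-06, and adjusted p = 0.00961 with an estimated correlation). Id2 rose 2.12-fold, Arg1 3.62-fold and the leukotriene receptor gene Ltb4r1 5.55-fold. Il1rl1 rose 3.37-fold, a call lost without wild-type replicate 1 or 2 (adjusted p up to 0.0634). Gata3, at 53.6 ± 7.84 and 49.4 ± 6.01 CPM, and Il17rb, at 74.7 ± 5.66 and 75.0 ± 8.79 CPM, were not called, and Klrg1 was at 2.26 ± 1.21 and 5.47 ± 1.38 CPM (adjusted p = 0.125).

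Of 18 NF-kB and TNF receptor genes 7 rose (13 adjusted over the list alone; adjusted p = 2.08e-20, and adjusted p = 0.00309 with an estimated correlation). Among them were Tnfrsf9 (3.53-fold), Tnfrsf18 (1.83-fold) and Nfkbia (1.74-fold). Of 10 thymus regeneration ligands 5 rose (6 adjusted over the list alone, adjusted p = 3.39e-18, and adjusted p = 0.00489 with an estimated correlation), including Ltb (1.78-fold) and Il22, a cytokine that acts on epithelium, from 3.38 ± 2.04 to 13.3 ± 2.96 CPM. Il13 and Areg, counted above as type 2 effectors, belong to this list too. Of its 12 members found in the knockout experiment, 6 are in another list, so these list calls are not independent. Of 13 inflammatory ILC2 genes 3 rose (6 and 1 lower adjusted over the list alone; adjusted p = 6.85e-07, and adjusted p = 0.0157 with an estimated correlation). Il17a rose from 3.11 ± 2.49 to 15.7 ± 4.77 CPM and S100a4 from 35.8 ± 9.87 to 101 ± 19.9 CPM. Of 14 residency genes 2 rose (3 adjusted over the list alone; adjusted p = 0.00124, and adjusted p = 0.0471 with an estimated correlation), the chemokine receptor gene Cxcr6 6.06-fold and Itgae 3.82-fold. Of 22 cytokine receptor and signalling genes 4 rose, also adjusted over the list alone (adjusted p = 0.00613, but adjusted p = 0.051 with an estimated correlation), with Il2rb 2.62-fold and Cish 1.59-fold higher. Of 41 cell cycle genes 0 were called over all genes (1 lower adjusted over the list alone), and the list was lower (adjusted p = 5.18e-05, and adjusted p = 0.0423 with an estimated correlation). Mki67 was at 95.4 ± 29.7 and 72.8 ± 6.92 CPM. Of 27 p53 genes 1 rose, also adjusted over the list alone (adjusted p = 0.775). It was Cdkn1a, from 381 ± 33.2 to 533 ± 27.4 CPM, a call lost in 7 of 8 fits with 1 library left out (adjusted p up to 0.119).

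Of 74 oxidative phosphorylation genes 2 rose, also adjusted over the list alone (adjusted p = 1.55e-05, but adjusted p = 0.283 with an estimated correlation). Of 78 ribosomal protein genes 3 rose (4 adjusted over the list alone; adjusted p = 2.43e-08, but adjusted p = 0.241 with an estimated correlation). Interferon (1 of 31 rose, also adjusted over the list alone; adjusted p = 0.99) and dissociation stress (2 of 20, also adjusted over the list alone; 0.227) were not called as lists. Neither were apoptosis (1 of 18 rose; 1 and 1 lower adjusted over the list alone; 0.695) and glycolysis (0 of 15, also adjusted over the list alone; 0.0839), which was called without wild-type replicate 3 (0.0314). Atf3, a stress-induced regulator, rose 2.06-fold and the proapoptotic gene Bik 3.84-fold. Markers of several other cell types moved beside the effector genes. Of 6 ILC3 markers 3 rose (4 adjusted over the list alone; adjusted p = 1.26e-09, and adjusted p = 0.00934 with an estimated correlation), namely Il17a, Il22 and Il18r1, which rose from 1.47 ± 0.76 to 8.55 ± 2.76 CPM. Of 8 myeloid and dendritic cell markers 4 rose (5 adjusted over the list alone; adjusted p = 3.6e-07, and adjusted p = 0.0289 with an estimated correlation), with H2-Aa up from 5.73 ± 1.24 to 19.3 ± 4.89 CPM. Of 5 NK cell and ILC1 markers Gzmb rose, also adjusted over the list alone (adjusted p = 0.0011, and adjusted p = 0.0396 with an estimated correlation). Of 12 T cell and thymocyte markers Dntt fell (2 adjusted over the list alone), and the list was lower (adjusted p = 0.000366, and adjusted p = 0.0471 with an estimated correlation). Of 8 stromal, epithelial and endothelial markers the keratin gene Krt8 rose, from 4.76 ± 2.96 to 23.2 ± 7.59 CPM (2 adjusted over the list alone; adjusted p = 0.712 for the list). Cd79b with Fcmr and Cpa3 with Siglecf were the only tested B cell and mast cell or eosinophil markers, and none was called. Without knockout replicates 3 and 4, a choice made after the data were seen, 88 genes were called and 25 of the 53 called genes that the naming rule took lost their calls. Of the genes named here these were Il1rl1, Il5, Cdkn1a, Arg1, Bik, Dntt, Krt8 and Nfkbia (adjusted p = 0.0547 to 0.221). The lists of oxidative phosphorylation, ribosomal proteins and NK cell markers lost theirs too (adjusted p = 0.286, 0.302 and 0.0766). Of the 53, 37 were called in every fit with 1 library left out, and the called genes named here are among them unless a lost call is given.

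**Figure D3:**
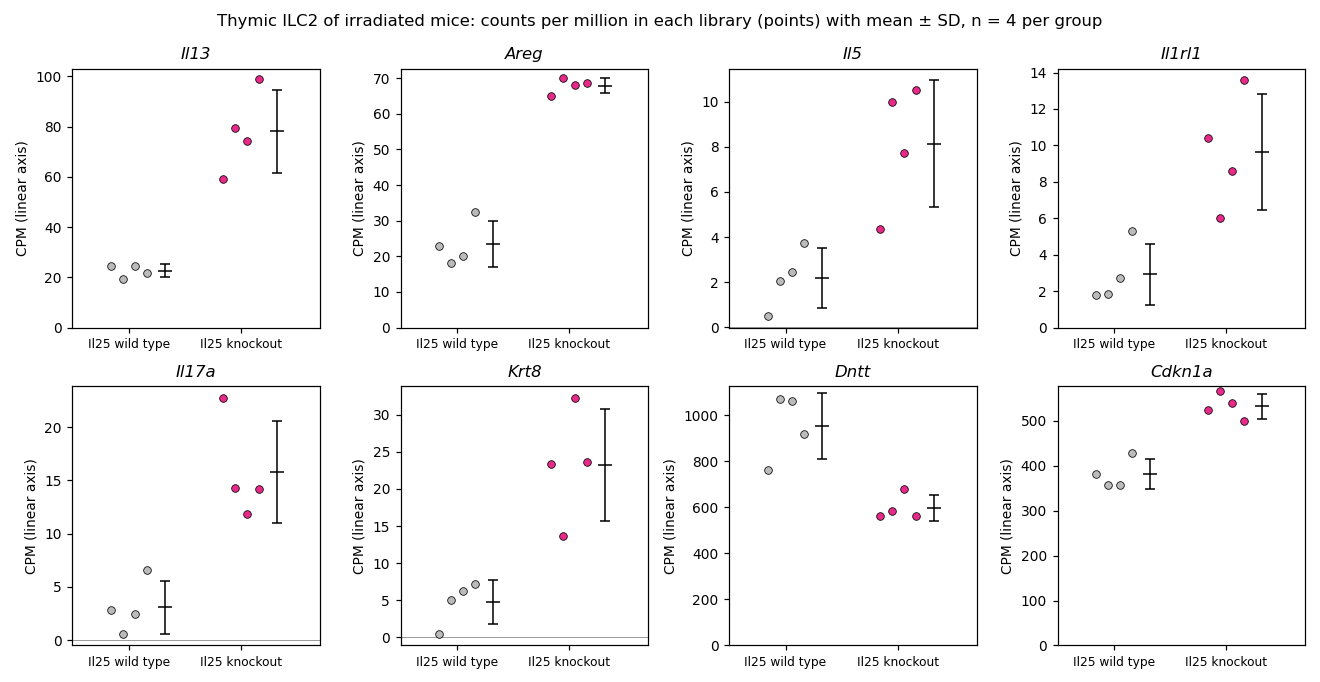
Levels of 8 genes in the 8 libraries of the knockout experiment, in CPM, with each library as a point and the mean ± SD of each group of 4 as a bar. Il13 averaged 22.6 CPM in Il25 wild-type and 78.1 CPM in Il25 knockout mice, and Dntt 953 and 597 CPM.

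The treated groups were compared with each other through their changes against the same untreated libraries. Irradiation alone and both treatments shared 100 genes called higher and 74 called lower, where independence would give 7.01 and 6.35, and 1 gene, Rpl39, was called in opposite directions. Across 7482 genes, which are not independent replicates, their log2 changes correlated with r = 0.683, against 0.488 in 20 simulations of unchanged groups that shared the controls, and their covariance was 0.347 against 0.0599. For rIL-25 and irradiation r was 0.511 against 0.493 simulated (covariance 0.14 against 0.06), and for rIL-25 and both treatments 0.302 against 0.521 (covariance 0.0954 against 0.0597). The simulated groups held no treatment effect. Effects in 1 group widen the spread of its changes and can lower r. The value of 0.302 therefore does not show that these changes were less alike than those of unchanged groups. With 3 control libraries no split leaves at least 2 on each side, so part of the excess may come from the shared controls.

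The last comparison asked whether genes moved by rIL-25 or irradiation also differed without Il25, in libraries that share no sample with the first experiment. No gene was called for rIL-25 by edgeR (336 at an unadjusted p under 0.05) or DESeq2, so that list was empty. Of 154 measured genes that rose after irradiation, 19 were higher in the knockout and 6 lower (Endou, Gfra1, Myzap, Drc1, Slc16a5 and Pdlim4, the last lost without wild-type replicate 3 at an adjusted p of 0.0558), with a median log2 change of 0.04, and the list was higher (adjusted p = 0.0101). Of 125 measured genes that fell after irradiation, Nrgn was higher and Dntt lower (median 0.03, adjusted p = 0.677). Of 298 measured genes that rose after both treatments, a list added after the data were seen, 47 were higher and 6 lower (the same 6 genes; median 0.10, adjusted p = 1.82e-09). Of 322 that fell, 6 were higher and Dntt lower (median 0.04, adjusted p = 0.172). The genes that rose when rIL-25 was added to irradiation (42 measured, median 0.09, adjusted p = 0.0134, but p = 0.102 with an estimated correlation) included Il13, Cxcl10, Cish and Dgat2, which were higher in the knockout. Those that fell (130 measured, median 0.20, adjusted p = 0.000489, but p = 0.385 with an estimated correlation) included Rps4x, the 1 gene called in the knockout, where it was higher, a call lost in 6 of 8 fits with 1 library left out (adjusted p up to 0.123). Across 6980 genes the log2 changes of the knockout correlated with those of rIL-25 with a Pearson r of 0.25 and a Spearman rho of 0.099. The values were 0.176 and 0.125 with those of irradiation. They were 0.142 and 0.047 with those of both treatments, and −0.014 and −0.041 with those of rIL-25 added to irradiation. Endou, Gfra1, Slc16a5 and Nrgn were named after their values were seen.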

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

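Among the tests below, those of the doubly treated libraries that stood apart, of the thymocyte share and of depth as the source of the fold changes were chosen after the result was seen.

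In 11 of 212 groups of 4 libraries in the knockout experiment, 1 library lay far from the other 3 by Dixon's ratio of gap to range, which chance gives for about 1 in 20 groups. In Il25 wild-type mice these were Gng13 (ratio 0.982, 9.68 CPM in replicate 4 against at most 1.43 in the others) and Pecam1 (0.941, 61.4 against 38.4 in replicate 2). They were also Bcl2l11 (0.923, 92.4 against 107 in replicate 3), Fosb (0.875, 55.8 against 65.5 in replicate 1) and H2-Ab1 (0.859, 22.3 against 32.6 in replicate 2). In Il25 knockout mice they were Pusl1 (0.968, 35.3 against 3.18 in replicate 2) and Themis (0.904, 43.2 against 53.9 in replicate 1). They were also Ccl5 (0.876, 24.5 against 16.2 in replicate 3), Spi1 (0.874, 13 against 8.92 in replicate 1), C1qtnf12 (0.832, 30 against 9.44 in replicate 2) and Dntt (0.83, 681 against 582 in replicate 3).

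The effect of irradiation differed between mice with and without rIL-25, by the interaction test, for 18 named genes. The difference in log2 change was higher with rIL-25 for Mettl20 (2.98 ± 0.77), Oard1 (2.42 ± 0.54), Bccip (2.40 ± 0.40), Tef (2.24 ± 0.54) and Bcl11b (1.06 ± 0.27). It was lower for Rpl39 (−3.85 ± 0.42), Cept1 (−3.76 ± 0.62), Dbt (−3.13 ± 0.70), Uqcrb (−3.07 ± 0.49), Cox7b (−2.88 ± 0.45) and Ndufa5 (−2.63 ± 0.38). It was also lower for Ccng1 (−1.89 ± 0.39), Rps24 (−1.85 ± 0.39), Hsp90aa1 (−1.78 ± 0.38), Rpl36a (−1.72 ± 0.29), Ndufa1 (−1.60 ± 0.26), Ccna2 (−1.59 ± 0.37) and Rpl31 (−1.47 ± 0.27). Mettl20, Oard1, Tef, Dbt, Bcl11b, Ccng1, Ccna2, Hsp90aa1 and Rps24 each lost this call in at least 1 fit with a library left out.

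The 140 genes lower after both treatments than after irradiation alone, led by Rpl39, Cox7b and Uqcrb, had a median GC content of 39.2% against 45.2% for all tested genes, but an offset for GC content left 90.7% of them called lower with a median change 0.972 times as large, which argues against a GC trend. Whether the calls rest on replicates 1 and 3 of the doubly treated group cannot be told apart: all 140 genes lay below the irradiated mean in each replicate (medians −1.46, −0.93 and −1.64), but they were chosen with these libraries. Genes chosen without replicate 2 had a median of −0.60 there (244 of 270 lower) against −1.48 in replicates 1 and 3. Between replicate 2 and an irradiated library that were both left out of the choice, the medians were −0.524, −0.475 and −0.496 (159 of 187, 199 of 236 and 158 of 201 genes lower): the direction held in replicate 2 at a smaller size, and the last pair missed the bound, which was below −0.5 for each. A response to rIL-25, or to its injection, in irradiated mice stays open, untested. High values in the irradiated group, which the choice of genes favours, stay open too (medians of −0.57 in untreated mice and −0.099 after rIL-25, relative to the irradiated mean).

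Il13, Areg, Ccl1 and other effector genes were higher in libraries of sorted ILC2 of Il25 knockout mice. A lower share of thymocyte-like RNA stays open, because other cell types need not rise alike when that share falls. The exact tests of list medians also had genes, not libraries, as their units. The type 2 effector median, 1.497, exceeded that of NK cell markers by 1.243 (exact test, p = 0.0234, adjusted p = 0.0468). Stromal markers were exceeded by 1.85 (exact test, p = 0.00241). No excess was detected over myeloid markers (difference 0.726, exact test, p = 0.12). The same held for the second tuft cell list (0.631, exact test, p = 0.107) and ILC3 markers (−0.13, exact test, p = 0.804). RNA of tuft cells fits in that a second tuft cell list rose too (median 0.866, p = 0.000215, and p = 0.0159 with an estimated correlation), although 1 of its 7 members was called over all genes (3 adjusted over the list alone), Krt18 at 13.8 and 36.6 CPM, a call lost without wild-type replicate 2 or 3 or knockout replicate 3 (adjusted p up to 0.075), and none of this shows that tuft cells carried Il13. Thinning every library to 2093288 counts left 11 or 12 of 13 called members above the filter. Their medians were at least 1.484 on the log2 scale and 0.957 times those of the same members before. Random thinning keeps each gene's expected share of a library, so it could not test depth as the source of the folds. In the lowest of 5 draws 8 of the 13 calls stayed, so how far the calls depend on depth cannot be told apart. An effect of losing Il25 stays open beside a changed mix of sorted cells.

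Dntt, Cpa3 and Hoxa7, grouped as genes of early lymphoid or progenitor cells after their values were seen, were lower after irradiation, while the list of T cell and thymocyte markers that holds Dntt was higher (adjusted p = 5.79e-05). An offset for GC content left 91.1% of the 135 genes called lower with a median change 1.004 times as large, which argues against a GC trend. Fewer early progenitor-like cells in the sort cannot be told apart from a change within ILC2: a second list of 9 progenitor genes, with 1 higher and 1 lower, had a median of −0.425, short of its bound of −0.5, and was not called (p = 0.234, and p = 0.306 with an estimated correlation). No bound was set for the comparisons of both treatments with another group. In them the median of this list was −1.2 against rIL-25 (p = 0.00627, and p = 0.0403 with an estimated correlation). It was −0.959 against untreated (p = 0.04, but p = 0.0932 with an estimated correlation) and −0.22 against irradiated (p = 0.267). After irradiation alone Ly6a was higher (55.0 ± 12.5 and 210 ± 70.1 CPM) and Lyl1 lower (127 ± 37.3 and 49.3 ± 11.8 CPM), a call that Lyl1 lost without untreated replicate 3 or irradiated replicate 1 (adjusted p up to 0.0616).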

How the results depend on the processing

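Named genes kept their direction and side of the threshold in 11524 of 12431 values under the alternatives fixed beforehand, with 543 weaker, 215 stronger, 149 moved and 0 reversed. They did so in 1403 of 1708 values under alternatives added after the data were seen (216 weaker, 46 stronger, 43 moved, 0 reversed). Thinning the knockout libraries to 2093288 counts each gave 116 to 129 calls in 5 draws, against 156 at full depth; how far depth limits the other comparisons was not tested.

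List tests kept their direction and side of the threshold in 1819 of 2064 values under the alternatives fixed beforehand (75 weaker, 71 stronger, 99 moved, 0 reversed) and in 292 of 344 under added ones (15 weaker, 11 stronger, 24 moved, 2 reversed). Lists called in neither fit count as kept here too. Of the 75 weaker values, 38 came with an estimated correlation and 34 with 1 library left out. The others were dissociation stress (irradiated) and inflammatory ILC2 (rIL-25) with no filter, and inflammatory ILC2 (both treatments against rIL-25) with DESeq2's size factors. No filter gave 7 new list calls, the replicate block 2, and the GC offset 4, while the offset ended that of inflammatory ILC2 (against rIL-25). Without doubly treated replicates 1 and 3, calls ended for glycolysis (against untreated), ILC2 identity, dissociation stress and NF-kB (against irradiated), inflammatory ILC2 and glycolysis (against rIL-25) and myeloid markers (interaction), with 3 new ones, beside the 2 reversed ribosomal lists given below. Without irradiated replicate 2 and rIL-25 replicate 3 they ended for type 2 effectors, inflammatory ILC2 and residency (rIL-25) and myeloid markers (interaction), with 4 new ones.

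Counts of called genes that moved by over 1.5 times were 742 (both treatments against rIL-25) and 92 (knockout) with a threshold of 2-fold, 541 (irradiated against untreated) and 417 (interaction) with limma voom, and 125 (both treatments against irradiated) with only the 2 groups fitted. Without doubly treated replicates 1 and 3, which left 1 library assumed to vary like the other groups, they were 37 (against untreated), 0 (against irradiated), 34 (against rIL-25) and 1 (interaction), and the median of ribosomal protein genes reversed to 0.186 (against untreated, where the list became called higher, adjusted p = 0.00519) and 0.065 (against rIL-25, where its call ended, 0.463). Without knockout replicates 3 and 4 the count was 88. Without irradiated replicate 2 and rIL-25 replicate 3 the counts were 412, 0, 762, 192, 1078 and 140 in the order of the 6 treatment comparisons. With 1 library left out they ranged from 86 (untreated 3) to 370 (irradiated 2) for irradiated, 0 to 3 for rIL-25, and 271 (doubly treated 3) to 896 (doubly treated 2) for both treatments against untreated. They ranged from 42 to 358 against irradiated and 460 to 1318 against rIL-25 (without the same libraries), 29 (untreated 1) to 347 (untreated 2) for the interaction, and 105 (wild type 2) to 174 (wild type 4) for the knockout.

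With the replicate number as a block, which does not pair samples by the design, the counts were 325, 0, 679, 212, 1131, 162 and 151. DESeq2 gave 292, 0, 568, 215, 894, 190 and 195. The correlation of irradiation and both treatments, 0.683, was 0.646 with no filter, 0.631 to 0.739 with 1 library left out, 0.637 without irradiated 2 and rIL-25 3, and 0.557 without doubly treated 1 and 3. In the knockout the genes that fell after both treatments had medians of 0.11 (list from DESeq2) and 0.108 (at least 2-fold) and became called (p = 0.0348 and 0.0252, but p = 0.339 and 0.277 with an estimated correlation). Those that rose against irradiated lost their call with DESeq2 (0.051) and with an estimated correlation (0.086), and those that fell with an estimated correlation (0.196). Beyond what fewer samples, fewer genes or a stricter threshold explain, the cause was not tested.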

Other observations

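Of 9 early progenitor genes outside the fixed lists, a list added after the data were seen, 1 was higher, 3 lower and 5 not called after both treatments against untreated mice (list p = 0.04, but p = 0.0932 with an estimated correlation). Against rIL-25 alone 1 was higher, 4 lower and 4 not called (list p = 0.00627, and p = 0.0403 with an estimated correlation). In the knockout 0 of 10 were called and the list was higher (p = 0.00396, and p = 0.0237 with an estimated correlation). Myb, a regulator of blood progenitors, fell from 482 ± 103 to 246 ± 19.9 CPM against untreated mice (n = 3 per group, adjusted p = 0.00411) and Lyl1 fell from 127 ± 37.3 to 53 ± 16.2 CPM, while Ly6a rose from 55.0 ± 12.5 to 200 ± 62.6 CPM. The third lower gene, Cd93, lost its call against untreated mice without untreated replicate 2 or doubly treated replicate 3 (adjusted p up to 0.138). Against rIL-25 alone Cd93 fell from 91.3 ± 11.3 to 34.3 ± 15.1 CPM, beside Myb, Lyl1 and Igf1r (the last named after its value was seen), and Ly6a lost its call without rIL-25 replicate 1 or doubly treated replicate 2 (up to 0.0989). Outside the list Cxcl10 had a count ratio of 32.5 against rIL-25 (95% interval 10.8 to 161). In the knockout experiment Prr29 rose 10.4-fold (n = 4 per group) and Hs3st1 6.42-fold.

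Single libraries and genes stood out as values. Replicate 3 of the rIL-25 group had 63.6 CPM of Il13, 48.3 of Klrg1, 362 of H2-Aa and 158 of Lyz2, against at most 9.46, 4.73, 11.5 and 20.4 in the other rIL-25 libraries. Irradiated replicate 2 had 15.7 CPM each of Krt8 and Ltc4s, where the other irradiated libraries had 0. Areg had 0 counts after irradiation and 5, 1 and 52 in replicates 1 to 3 after both treatments. Gapdh ranged from 1.40 to 282 CPM in untreated, 9.79 to 897 in irradiated and 21.0 to 1140 in knockout libraries, and Rpl39 from 13.5 to 442 CPM across the knockout experiment.

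The authors' adjusted p-values equal Benjamini-Hochberg values of their p-values for every gene in 5 of their 7 comparisons. For untreated against rIL-25 they equal them for 0 genes, with 3 genes under 0.05 against 0 recomputed. For rIL-25 against both treatments they also equal them for 0 genes, with 51 against 858 recomputed; the cause was not tested.

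Lists fixed beforehand whose median, mean and test differed in sign, none called except cytokine receptors after both treatments, were apoptosis and stromal (irradiated against untreated), cytokine receptors (rIL-25), apoptosis and cytokine receptors (both treatments against untreated), residency, p53 and T cell (against irradiated). They were also interferon, stress, apoptosis, oxidative phosphorylation and stromal (against rIL-25), ILC2 identity, type 2 effectors, p53, cell cycle, T cell, stromal and cytokine receptors (interaction), and p53, interferon and stromal (knockout). The same held for the tuft cell list added after the data were seen, for irradiated, rIL-25 and both treatments against untreated and for the interaction.

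Other splits of the same libraries tested whether a grouping by chance gives as many calls. The real split alone reached its count, 1 of 10 splits, for irradiated against untreated and for both treatments against untreated, irradiated and rIL-25, where other splits gave at most 2, 0, 1 and 0 calls; 10 splits are too few to tell. For rIL-25 all 10 of 10 splits gave at least 0 calls, with up to 11. For the interaction 2 of 100 splits reached 155, and the other, with 906 calls, put all 6 irradiated libraries on 1 side. These splits did not keep the separate effects of irradiation and rIL-25, so they cannot tell whether the 155 interaction calls arise by chance. For the knockout 1 of 35 splits reached 156, and the others gave at most 1.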
